A study of Mus musculus with 47 samples.

How the data were processed

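RNA of 47 samples was measured on arrays with 22690 Affymetrix mouse probe sets; the array model is not given in the sources used here. Per the labels' protocols, JB6 cells grown in medium with 5% fetal bovine serum received an shRNA against AnxA2 or the empty vector by retrovirus and were selected with puromycin. The labels state that AnxA2 RNA was lowered by more than 95%, and name Western blot and in situ hybridization for it; neither was analysed here. Per the labels, cells were exposed to X-rays in an X-RAD 320 cabinet or sham-treated, RNA was isolated with RNeasy columns, and 3 µg was labelled by the one-cycle protocol. Per the submitters' processing notes, signals were summarised by RMA. The version of the RMA software is not given in the sources used here. The deposited values are RMA signals on the log2 scale, between 1.84 and 14.03, and were used as the authors deposited them. No 2 arrays were identical, and 0 value columns were left unused. Raw array files were not analysed here.

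Samples were grouped by line, dose and time as the labels give them, into 16 groups of 3 arrays, except 10 cGy vector cells at 24 h, with 2 arrays (replicates 1 and 3). No group of untreated cells at 6 h is among the samples used here. The labels number the replicates but do not say what the numbers share. 64 control probe sets were set aside. Of the others, 20380 have exactly 1 gene symbol in the platform annotation, 691 several and 1555 none; the last 2 kinds were left out. For 20351 probe sets the Entrez number was found in the RefSeq table of GRCm38.p6, and 0 symbols needed an update. That table served for names, positions and the order of genes on chromosomes. These probe sets cover 12393 genes, 4956 of them with more than 1 probe set. For each gene the probe set with the highest mean over all arrays was used. The 30% of genes with the lowest mean (log2 mean under 4.35) were left out, which left 8675 tested genes. Among the named and called genes, 88 gene and comparison pairs had another tested probe set; in 85 all probe sets moved the same way, and in 0 was another called in the opposite direction. The other 3 pairs are all Scara5.

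A single limma fit of the 16 group means to all 47 arrays gave every contrast, with moderated variances (31 residual and 5.68 prior degrees of freedom). Groups of 1 or 2 arrays, also when an array was left out, are thereby taken to vary like the other groups. P values were adjusted by Benjamini-Hochberg over the genes of each contrast, with a threshold of 0.05, and are two-sided. The contrasts were shRNA against vector in untreated cells, each dose against untreated in each line and time, the difference of these responses between lines, 100 against 10 cGy over both lines at each time, and 24 h against 2 h in untreated cells. Responses at 6 h were taken against the mean of the untreated 2 h and 24 h groups. Gene lists were tested with camera at a preset correlation of 0.01, with adjustment over the lists of a contrast, and beside it with an estimated correlation and with fry, whose p tests whether a list's genes move one way on balance and compares them with no other genes. Over all 23 contrasts, 101 of 483 list tests passed camera, 40 of them also with an estimated correlation and 56 with fry. The lists were written before the data were examined, like the contrasts, the tests of genes and lists and most alternatives. They covered p53 targets, mitotic, DNA replication, DNA repair, interferon response, NF-kB inflammatory, immediate early and NRF2 antioxidant genes. Cholesterol synthesis, ATF4 and unfolded protein, hypoxia and glycolysis, annexin and S100 (without Anxa2) and plasminogen system genes were covered too. So were extracellular matrix and mesenchymal, epithelial and keratinocyte, actin cytoskeleton and adhesion, heat shock, apoptosis, leukocyte, muscle and reference genes. 2 further lists of cell type markers had 4 tested members each, under the minimum of 5, and were not tested. The median, the mean and the test had the same sign in every one of the 101 calls.

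Genes were named by a rule: Anxa2 in every group; for the line difference the 12 higher and 12 lower genes with the largest change, called, without overlap between arrays; for each 100 cGy response the 5 higher and 5 lower and for each 10 cGy response the 3 higher and 3 lower of this kind; for interaction, dose and time contrasts the 5 higher and 5 lower called genes with the largest change; up to 6 members of a list with the smallest p; and Cdkn1a, Mdm2 and Ccng1 always. Genes outside the rule are said to have been chosen after their values were seen.

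The method was tested on simulated data with 200 changed genes of 8675. At a log2 change of 1 it recovered 100% of them for the line difference, 96% for 100 cGy at 2 h in vector cells, 91% for the interaction at 24 h and 100% for dose at 6 h, and at 0.5 it recovered 91%, 65%, 32% and 91%. Between 1.55% and 8.52% of the simulated calls were false. The simulated noise was independent between arrays, with a single spread for each gene. These rates therefore leave out correlated replicates and arrays that stand apart, which the real data hold. In a contrast without simulated changes 0 genes were called in 3 of the simulations and 1 in the other; that contrast, dose at 24 h, replaced one that shared groups with the changed contrast.

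Whether equal replicate numbers share a culture or day was checked from the correlation of residuals between arrays of equal number. All 3 pairs were correlated for 100 cGy against untreated vector cells at 2 h (0.51, 0.34 and 0.63) and at 24 h (0.20, 0.27 and 0.15), and for 100 against 10 cGy at 2 h in vector (0.48, 0.48 and 0.72) and shRNA cells (0.48, 0.48 and 0.36), and at 24 h in shRNA cells (0.19, 0.51 and 0.56). With 2 pairs only, too few to judge by the same rule, were 10 cGy against untreated vector cells at 24 h (0.13 and 0.34) and 100 against 10 cGy there (0.19 and 0.13). The other pairs of groups checked had at least 1 value under 0.1. Residuals of a group sum to 0 for each gene, so the values for 2 groups are not separate evidence. In vector cells at 2 h, a shift shared by the replicate 3 arrays, which stood apart, would alone correlate all 3 pairs. The check therefore cannot tell there whether equal numbers share a culture or day. 1 fit without a block served every contrast, and a replicate block within line and time is among the alternatives.

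The alternatives set in advance were no filter on low values, leaving out the lowest 50%, each of the 15838 probe sets above the lowest 30% counted by itself, also those without a gene, quantile normalization of the values again, only the compared groups in the fit, a replicate block over all groups, a trend and robust variance prior, array weights, either untreated time alone for the 6 h contrasts, and leaving out each array in turn. Added after the data were seen were the fit without the 3 vector arrays at 2 h that stood apart, a replicate block within each line and time, contrasts within a line or condition, and the count of genes that differ at 6 h from both untreated times. Principal components were computed on the centred values of the tested genes. R 4.3.3 with limma 3.58.1 made the fits, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the tables and drew the figures. A small number of gene results are not reported here.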

Results

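The data were RNA levels measured on 47 Affymetrix mouse arrays, 1 per RNA sample, in JB6 cells, a mouse epidermal line used to study tumour promotion. 1 line carried a retroviral short hairpin RNA (shRNA) against Anxa2, and the other carried the empty vector. Anxa2 encodes annexin A2, a calcium-dependent phospholipid-binding protein that forms a complex with S100A10 and binds plasminogen. Cells of each line were sham-treated or given 10 or 100 cGy of X-rays. RNA was collected at 2, 6 and 24 h after irradiation, and at 2 and 24 h from sham-treated cells, called untreated here. These conditions make 16 groups of 3 arrays each, except vector cells at 24 h after 10 cGy, with 2. There is no untreated 6 h group. The comparisons ask how cells with less Anxa2 differ from vector cells, how each line responds to each dose over time, and whether the lines respond differently. The number of arrays limits the precision of every value. All changes below are log2 differences between group means with the standard error from a limma fit, and adjusted p values are Benjamini-Hochberg values over 8675 tested genes. "Rose", "fell" and "changed" are used at an adjusted p under 0.05.

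Anxa2 (chromosome 9, 69453683 to 69491792, GRCm38.p6) was lower in shRNA cells in every condition. In untreated cells it was lower by a log2 difference of -1.55 ± 0.06 (adjusted p = 3.38e-23), which left 34.2% of the vector level (95% interval 31.5% to 37.1%), with no overlap between the 6 arrays of each line. The labels state a loss of the RNA above 95%, larger than the loss of signal here. Array signals can be compressed and hold background, so this percentage of signal may differ from the share of RNA left. The shRNA group means given below lie well above the filter limit of 4.35, and the cause of the gap was not tested. By condition, Anxa2 stood at 37.3% of the vector level in untreated cells at 2 h and 31.3% at 24 h. After 10 cGy it stood at 37.4%, 37.7% and 32.0% at 2, 6 and 24 h, and after 100 cGy at 34.0%, 35.4% and 31.9%. Group means of log2 signal ran from 10.70 to 11.16 in shRNA cells and from 12.34 to 12.61 in vector cells. These values are from the Anxa2 probe set with the highest signal. Of the others, 1 ran from 5.97 to 6.16 against 6.65 to 6.92, and 1 lay near the bottom of the scale in both lines (2.35 to 2.58).

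**Figure D1:**
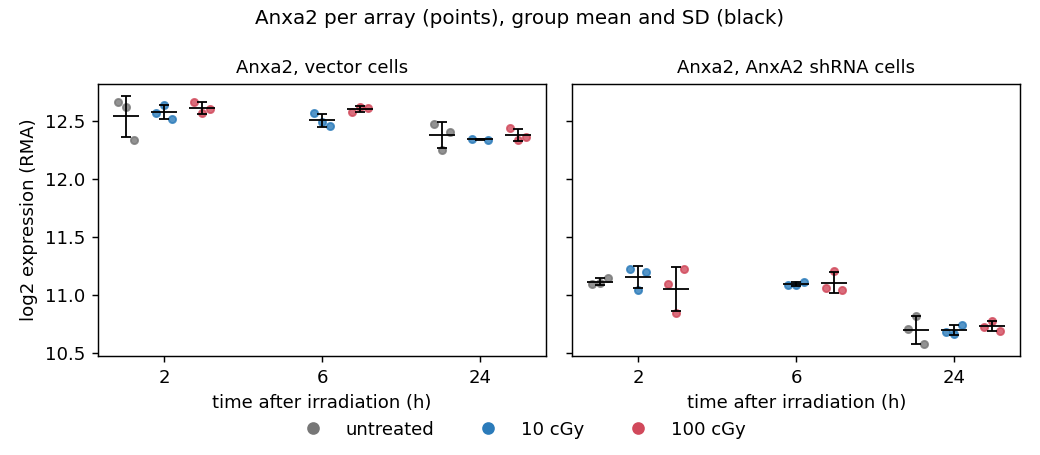
Log2 expression of Anxa2 on each array (points) with the group mean, by time after irradiation in hours and by dose, for vector and shRNA cells. Group means lie between 12.34 and 12.61 in vector cells and between 10.70 and 11.16 in shRNA cells.

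The line and the time in culture set the main structure of the arrays. The first principal component, with 51.3% of the variance, parted shRNA arrays (-25.44 to -21.20) from vector arrays (20.74 to 27.61). The second, with 19.5%, followed time: 24 h arrays lay at 18.30 to 20.62 in vector cells and 15.68 to 19.01 in shRNA cells. 3 vector arrays at 2 h, replicate 3 of the untreated, 10 cGy and 100 cGy groups, stood apart from the other 6 vector arrays at 2 h. They lay at -2.37 to 1.75 on the second component, against -19.56 to -16.91 for the other 6. Across genes, which are not independent replicates, their shift from their group mates correlated with the change from 2 to 24 h in vector cells of the other 2 treatments, computed without these 3 arrays (r = 0.41 untreated, 0.56 at 10 cGy, 0.63 at 100 cGy). The untreated one of these arrays also had a raised Gapdh 3' minus 5' signal difference, a sign of RNA quality (0.594, against at most 0.111 on the other 6). High values also occurred on 3 shRNA arrays: 10 cGy 6 h replicate 1 (1.06), 100 cGy 2 h replicate 2 (0.492) and untreated 2 h replicate 1 (0.309).

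**Figure D2:**
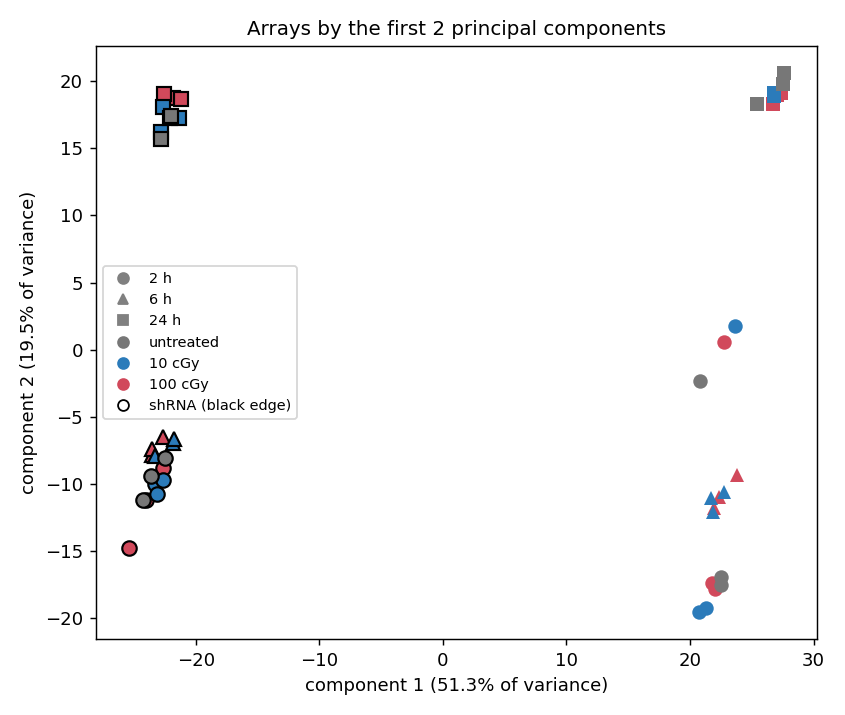
Each point is an array placed on the first (51.3% of variance) and second (19.5%) principal components of the log2 values, with marker shape for time and colour for dose; vector arrays lie at 20.74 to 27.61 and shRNA arrays at -25.44 to -21.20 on the first. 3 vector arrays at 2 h lie at -2.37 to 1.75 on the second component, between the other 2 h and the 24 h arrays.

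In untreated cells, the 2 lines differed widely (shRNA minus vector, 2 and 24 h together, 6 arrays per line). For 14 of the genes named next, 1 line had a mean under 4.35, the low-signal limit of the filter. For these the fold is given as a bound, the higher line's mean over that limit (or over an array's own value where higher). The limit is a percentile of all genes and no measured background. In shRNA cells Cdh11, a cadherin of mesenchymal cells, was at least 41.8-fold lower (adjusted p = 3.92e-38), the stromelysin gene Mmp3 at least 22.9-fold, the collagenase gene Mmp13 15.5-fold, and the matricellular protein genes Smoc2 15.2-fold and Sparcl1 7.03-fold. Gpx7, a glutathione peroxidase, was at least 10.1-fold lower, Ahr, the aryl hydrocarbon receptor, 7.46-fold and Armcx4 6.49-fold. Pawr (-3.90 ± 0.11), a promoter of apoptosis, Tcim (-3.84 ± 0.25) and Mgst2 (-3.78 ± 0.16), a microsomal glutathione transferase, fell too. Rhox5, a homeobox gene of reproductive tissues, was 34.4-fold higher (5.11 ± 0.09, adjusted p = 1.12e-33). Slurp1, a secreted protein of keratinocytes (4.30 ± 0.15), Ankrd1, a cardiac ankyrin repeat protein (4.10 ± 0.28), the small heat shock protein gene Cryab (3.61 ± 0.19), cardiac troponin T, Tnnt2 (3.46 ± 0.08), and the transcription factor gene Klf2 (3.08 ± 0.08) rose as well. Mfap5, a microfibril protein, was at least 13.5-fold higher, Ptger4, a prostaglandin E2 receptor, 8.80-fold, the protease inhibitor gene Serpinb1a 8.20-fold, Afp, the fetal serum protein alpha-fetoprotein, 7.66-fold, Syce2 of the synaptonemal complex 7.03-fold and the GTPase gene Rab12 6.57-fold. For each of these genes the arrays of the lines did not overlap.

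Of the gene lists fixed in advance, NF-kB inflammatory genes fell as a group in shRNA cells. 16 of 25 members fell and 4 rose (17 and 4 adjusted over the list alone), with Birc3 (-1.55) and Saa3 (-1.28) among the lower ones. At the single times, tested after the data were seen, Saa3 was higher at 2 h (0.63) and lower at 24 h (-3.20). The list's camera adjusted p was 1.72e-05 (adjusted p = 1.10e-04 with an estimated correlation). Annexin and S100 genes other than Anxa2 were mostly higher, with 11 of 17 higher and 1 lower (13 and 1 adjusted over the list alone), among them Anxa8 (1.5), Anxa3 (0.92) and Anxa5 (0.47). Of 41 actin and adhesion genes 20 rose and 4 fell (21 and 4 over the list alone), among them the caveola gene Cav1 (0.61). Of 26 immediate early genes 13 rose and 3 fell (the same numbers over the list alone), including Klf4 (2.41), Dusp1 (2.19) and Jund (1.52). Of 20 interferon response genes 10 fell and 2 rose (12 and 2 over the list alone), including Rsad2 (-2.30), Irgm1 (-1.14) and Bst2 (-0.66). Of 20 NRF2 antioxidant genes 9 fell and 2 rose (the same over the list alone); Nqo1 (-1.70) and Gsta4 (-0.98) were lower and Cbr1 (0.92) was higher. The camera adjusted p was 0.00215 for annexins, 0.00288 for actin genes, 0.0037 for immediate early, 0.0134 for interferon and 0.0359 for NRF2 genes. None of these 5 passed with an estimated correlation (adjusted p = 0.304, 0.112, 0.315, 0.308 and 0.315). The extracellular matrix and mesenchymal list did not pass camera (adjusted p = 0.149), with 18 of 39 higher and 9 lower (18 and 10 over the list alone). The 6 called lists passed fry, which tests whether a list's genes move one way on balance and compares them with no other genes. Cdkn1a (0.44 ± 0.08) and Mdm2 (0.48 ± 0.08) were higher in shRNA cells. In all, limma called 2091 genes higher and 2094 lower, 48.2% of the 8675 tested. Of these, 172 and 223 differed at least 2-fold. With 1 shRNA line against 1 vector line, differences between the lines that do not come from Anxa2 loss are part of every one of these values. The labels do not say whether replicates are separate cultures, so all p values here measure the spread between samples, which may be technical.

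At 2 h after 100 cGy, vector cells raised 4 genes. Mdm2 (chromosome 10, 117688875 to 117710758), the p53-induced inhibitor of p53, rose 1.84-fold (0.88 ± 0.11, adjusted p = 7.67e-06). Cdkn1a (chromosome 17, 29090979 to 29100722), the p53-induced cell cycle inhibitor p21, rose 1.53-fold (0.61 ± 0.11, adjusted p = 0.00719). Phlda3, a p53-induced repressor of Akt (0.59 ± 0.10, adjusted p = 0.00233), and the thiamine transporter gene Slc19a2 (0.70 ± 0.10, adjusted p = 2.76e-04) rose with them, and no gene fell. Of 33 tested p53 targets 3 rose (8 adjusted over the list alone), and the list moved up (camera adjusted p = 4.82e-07; adjusted p = 0.00806 with an estimated correlation). Mitotic genes had a median of -0.08, with no member called by limma and 1 of 39 lower over the list alone (camera adjusted p = 0.00688, but adjusted p = 0.56 with an estimated correlation). Medians were -0.09 for extracellular matrix, -0.11 for DNA repair and 0.06 for annexin genes, with no member called over all genes or over the list alone. Their camera adjusted p values were 0.0218, 0.0272 and 0.0413, each adjusted p = 0.56 with an estimated correlation. 987 genes had an unadjusted p under 0.05. The count of 4 rose to 10 without 100 cGy replicate 3, 23 without untreated replicate 2 and 8 without untreated replicate 3, and dropped to 2 without untreated replicate 1; it was 14 without the 3 vector arrays that stood apart, 21 with a replicate block within line and time, and 0 with only the compared groups in the fit. Cdkn1a lost its call without 100 cGy replicate 1 (adjusted p = 0.0931) or 2 (0.229) and without untreated replicate 1 (0.0549) or 3 (0.128), and Phlda3 without untreated replicate 1 (0.0715).

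In shRNA cells at 2 h after 100 cGy, Slc19a2 (0.67 ± 0.10, adjusted p = 0.00129) and Mdm2 (0.63 ± 0.11, adjusted p = 0.00463) rose, and no gene fell. Cdkn1a had a value of 0.22 ± 0.11 (adjusted p = 0.909), and the test of the difference between the lines did not pass for Cdkn1a (-0.40 ± 0.16, adjusted p = 0.348) or for Mdm2 (-0.25 ± 0.15, adjusted p = 0.48). Ccng1, another p53 target, was not called in either line (-0.00 in vector and 0.25 in shRNA cells). Of 33 p53 targets 1 rose, the same number over the list alone (camera adjusted p = 0.0228; adjusted p = 0.56 with an estimated correlation). The difference between the lines passed for 1 gene, Myl6, a myosin light chain gene (-0.66 ± 0.12, adjusted p = 0.0177). 363 genes in shRNA cells and 1091 in the test of the difference had an unadjusted p under 0.05. Slc19a2 lost its call without 100 cGy replicate 1 (adjusted p = 0.0513), which left 0 genes, and Mdm2 without that array (0.0631) or untreated replicate 1 (0.081) or 3 (0.0606), each of which left 1; with only the compared groups in the fit 0 genes were called. The call on Myl6 was lost, leaving 0 genes, without shRNA 100 cGy replicate 1 or 2, shRNA untreated replicate 1 or 3, vector 100 cGy replicate 2 or vector untreated replicate 1 (adjusted p = 0.149, 0.0674, 0.0574, 0.161, 0.14 and 0.0801). It became 2 genes without vector 100 cGy or untreated replicate 3, and 5 without vector untreated replicate 2 or without all 3 vector arrays that stood apart. Across genes, the 2 h responses of the lines to 100 cGy had r = -0.26, which was 0.06 without shRNA 100 cGy replicate 2, the array with the Gapdh difference of 0.492, and -0.01 without the 3 vector arrays.

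**Figure D3:**
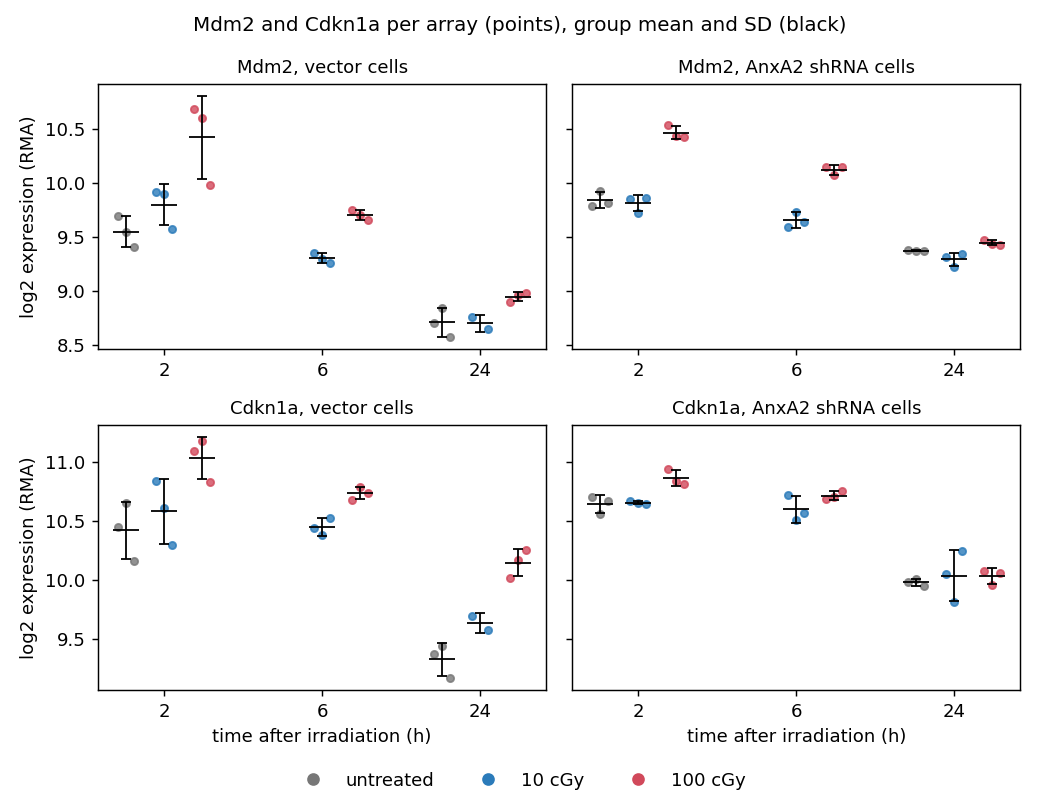
Log2 expression of the p53 targets Cdkn1a and Mdm2 on each array (points) with group means, by time after irradiation in hours, dose and line. At 2 h after 100 cGy, Mdm2 was higher by 0.88 in vector and 0.63 in shRNA cells; at 24 h Cdkn1a was higher by 0.82 in vector cells.

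At 2 h after 10 cGy, limma called 0 genes in vector cells (508 at an unadjusted p under 0.05). It called 1 gene lower in shRNA cells, Ttll3, a tubulin tyrosine ligase-like gene with means under the low-signal limit in both vector groups compared here (-0.94 ± 0.14, adjusted p = 7.70e-04; 388 genes at an unadjusted p under 0.05). Ttll3 was also the 1 gene whose response differed between the lines (-1.17 ± 0.20, adjusted p = 0.00857; 106 genes at an unadjusted p under 0.05). Cdkn1a had values of 0.16 ± 0.11 in vector and 0.01 ± 0.11 in shRNA cells, and Mdm2 0.25 ± 0.11 and -0.03 ± 0.11, none called. In vector cells the camera test passed for epithelial and keratinocyte genes (median 0.19), mitotic genes (-0.08) and DNA repair genes (-0.12), but not with an estimated correlation (adjusted p = 0.534 for each). In shRNA cells it passed for extracellular matrix (-0.14), DNA repair (-0.13), mitotic (-0.11) and leukocyte marker genes (0.14), with adjusted p = 0.642, 0.495, 0.885 and 0.495 with an estimated correlation. No member of any of these lists was called, over all genes or over the list alone. The 0 in vector cells became 7 without 10 cGy replicate 3, 5 without untreated replicate 3 and 10 without the 3 vector arrays that stood apart. The 1 in shRNA cells became 3 without 10 cGy replicate 3, 2 without untreated replicate 2 and 9 without those 3 vector arrays. Ttll3 lost its call in the difference between the lines without shRNA 10 cGy replicate 2 (adjusted p = 0.0908), shRNA untreated replicate 3 (0.068), vector 10 cGy replicate 3 (0.0618) or vector untreated replicate 1 (0.0742), and the count became 4 without vector untreated replicate 3 and 7 without those 3.

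At 6 h the irradiated cells were compared with the mean of untreated cells at 2 and 24 h, because untreated cells at 6 h were not measured. The values therefore hold any change that 6 h in culture brings, beside that of radiation. In vector cells at 6 h after 100 cGy, the chemokine genes Cxcl1 (-1.85 ± 0.17) and Cxcl5 (-1.81 ± 0.19), the serum amyloid gene Saa3 (-1.88 ± 0.12) and the adhesion molecule gene Vcam1 (-1.07 ± 0.08) fell. The Saa3 value rests on the untreated time: it was -0.38 against untreated 2 h cells alone (adjusted p = 0.0883) and -3.39 against 24 h cells. Hlf, a clock-controlled transcription factor (-1.86 ± 0.19, to a mean of 4.29, under the low-signal limit), the AMP deaminase gene Ampd3 (-1.77 ± 0.20) and the ferritin receptor gene Scara5 (-1.73 ± 0.14; the other tested probe set had the opposite sign, not called) fell too. Tnnt2 (2.09 ± 0.10), the metalloproteinase gene Adam12 (1.92 ± 0.10), the EGF receptor ligand gene Btc (1.89 ± 0.19), the drug efflux pump gene Abcb1a (1.80 ± 0.18) and the tubulin gene Tubb3 (1.70 ± 0.17) rose. The p53 targets Cdkn1a (0.86 ± 0.10) and Mdm2 (0.57 ± 0.09) rose. The p53 list did not pass camera, with 8 of 33 higher and 5 lower (8 and 6 over the list alone; adjusted p = 0.292). Of 37 DNA replication genes 20 fell (22 over the list alone), such as Rfc4 (-0.74), Rfc2 (-0.47) and Mcm3 (-0.51). Of 20 cholesterol synthesis genes 12 fell and 1 rose (14 and 1 over the list alone), such as Idi1 (-0.85), Lss (-0.75) and Sqle (-0.56). Of 25 NF-kB genes 9 fell and 1 rose (11 and 1 over the list alone); of 20 interferon genes 9 fell (11 over the list alone), such as Rsad2 (-1.93) and Trim30a (-1.01). Of 33 DNA repair genes 15 fell and 1 rose (17 and 2 over the list alone), such as Brca2 (-0.57) and Rad51c (-0.48). With an estimated correlation these 5 kept adjusted p = 3.20e-04, 3.41e-05, 3.41e-05, 0.0259 and 0.0463, and the muscle list 0.0463 on Tnnt2 alone, the 1 of its 5 members called. ATF4 and unfolded protein genes passed camera upward, with 10 of 30 higher and 2 lower (12 and 2 over the list alone), such as Nupr1 (1.07), but had adjusted p = 0.514 with an estimated correlation. In all 607 genes rose and 990 fell. Against untreated 2 h cells alone, Tnnt2 (0.24), Hlf (-0.58), Cdkn1a (0.32), Mdm2 (0.15), Rsad2 (-0.13), Idi1 (-0.28), Lss (-0.20), Sqle (-0.18), Rad51c (-0.16) and Nupr1 (0.61) were not called either; the lists were not tested against 1 untreated time.

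In shRNA cells at 6 h after 100 cGy, Cxcl1 (-1.65 ± 0.17), Cxcl5 (-1.56 ± 0.19), the pentraxin gene Ptx3 (-1.45 ± 0.14), the aggrecanase gene Adamts5 (-1.50 ± 0.14) and the clock-controlled transcription factor gene Dbp (-1.84 ± 0.26) fell. Ggct, a gamma-glutamylcyclotransferase (1.55 ± 0.15), Plek, pleckstrin (1.32 ± 0.19), the kinase gene Prkg2 (1.08 ± 0.08), the uridine phosphorylase gene Upp1 (1.08 ± 0.11), Btc (1.07 ± 0.19), Cdkn1a (0.40 ± 0.10) and Mdm2 (0.52 ± 0.09) rose. Of 33 DNA repair genes 13 fell and 1 rose (17 and 1 over the list alone), such as Brca2 (-0.67) and Xrcc6 (-0.45). Of 20 cholesterol synthesis genes 12 fell (14 lower and 1 higher over the list alone), such as Idi1 (-0.64) and Sqle (-0.53). Of 37 DNA replication genes 12 fell (14 over the list alone), such as Rfc4 (-0.61) and Rfc5 (-0.40). With an estimated correlation the adjusted p values were 0.0118, 7.52e-04 and 0.0118. In all 477 genes rose and 828 fell, a sum of 1305 that became 838, 844 and 843 without 100 cGy replicate 1, 2 or 3. Against untreated 2 h cells alone Cdkn1a (0.07) and Mdm2 (0.28) were not called. Against both times 6 of 33 p53 targets rose and 5 fell (7 and 7 over the list alone), and the list did not pass camera (adjusted p = 0.64).

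After 10 cGy at 6 h, 571 genes rose and 909 fell in vector cells. Among genes whose arrays did not overlap, Cxcl1 (-2.02 ± 0.17), Ampd3 (-1.86 ± 0.20) and the chemokine gene Ccl2 (-1.69 ± 0.26) had the largest losses, and Btc (1.97 ± 0.19), Adam12 (1.70 ± 0.10) and Abcb1a (1.69 ± 0.18) gains. Mitotic genes fell as a group, 25 of 39 (27 over the list alone), such as Cenpf (-0.62), Top2a (-0.59) and Nusap1 (-0.82), with adjusted p = 0.0159 with an estimated correlation. 17 of 20 cholesterol genes fell and 1 rose, 11 of 25 NF-kB genes fell and 1 rose, 11 of 20 interferon genes fell, and 15 of 37 DNA replication genes fell and 3 rose (over the lists alone, 17 and 1, 13 and 1, 12, and 18 and 3). Their adjusted p values with an estimated correlation were 2.64e-05, 3.37e-05, 0.0153 and 0.0153, and the muscle list had 0.0153 on Tnnt2 (1.98), 1 of 5 called. 3 further lists passed camera: DNA repair, with 10 of 33 lower and 1 higher (14 and 1 over the list alone), actin genes, with 5 of 41 higher and 2 lower (the same over the list alone), and ATF4 genes, with 8 of 30 higher and 2 lower (11 and 3 over the list alone). Their adjusted p was 0.132, 0.0964 and 0.578 with an estimated correlation. In shRNA cells 603 genes rose and 919 fell, led by Dbp (-1.81 ± 0.26), Cxcl5 (-1.60 ± 0.19) and Cxcl1 (-1.59 ± 0.17), and by Ggct (1.73 ± 0.15), Plek (1.37 ± 0.19) and the semaphorin gene Sema7a (1.27 ± 0.30) among those that rose. Of 33 DNA repair genes 16 fell and 1 rose (22 and 1 over the list alone), such as Brca2 (-0.74); of 37 DNA replication genes 13 fell and 1 rose (15 and 1), and of 20 cholesterol genes 10 fell (13 lower and 1 higher). With an estimated correlation these had adjusted p = 0.0104, 0.0156 and 0.00599. 19 of 39 mitotic genes fell (20 lower and 1 higher over the list alone), such as Cdk1 (-0.36) and Prc1 (-0.52), with camera adjusted p = 3.24e-07 but adjusted p = 0.169 with an estimated correlation. Cdkn1a rose in vector cells (0.57 ± 0.10) and in shRNA cells (0.29 ± 0.10, adjusted p = 0.0349), with no difference past the test between them (-0.29 ± 0.14, adjusted p = 0.385). The p53 list did not pass camera: 3 of 33 rose and 7 fell in vector cells (4 and 8 over the list alone; adjusted p = 0.285), and 2 rose and 5 fell in shRNA cells (the same over the list alone; adjusted p = 0.367). In shRNA cells the call on Cdkn1a was lost without 10 cGy replicate 1 (adjusted p = 0.201), the array with the Gapdh difference of 1.06, 10 cGy replicate 3 (0.0665), untreated 2 h replicate 2 (0.0732) or untreated 24 h replicate 1 (0.0526) or 3 (0.0552). Against untreated 2 h cells alone the value was -0.04, and in vector cells Cdkn1a (0.03), Ccl2 (-0.67) and Tnnt2 (0.13) and in shRNA cells Sema7a (0.30) were not called.

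Fewer genes differed at 6 h from both untreated times in the same direction, a comparison added after the data were seen: 408 in vector and 349 in shRNA cells after 100 cGy, and 306 and 427 after 10 cGy. In vector cells after 100 cGy they included Gadd45a, a stress-response gene, at -1.59 against untreated cells at 2 h and -1.67 at 24 h. Cxcl5 (-1.41 and -2.20), Cxcl1 (-1.03 and -2.68), Adam12 (1.33 and 2.52) and Trp53inp1 (1.16 and 0.97) were among them as well. In shRNA cells they included Cxcl5 (-1.69 and -1.43), Cxcl1 (-2.32 and -0.99), Ptx3 (-1.94 and -0.96), Adamts5 (-1.14 and -1.86), Upp1 (0.96 and 1.19) and the death receptor gene Fas (-0.82 and -1.03). Gadd45a, Trp53inp1 and Fas were chosen after their values were seen. The responses of the lines at 6 h, which share no arrays, correlated across genes (r = 0.68 after 100 cGy and 0.59 after 10 cGy), and of the genes called in both lines 751 moved the same way and 9 opposite ways after 100 cGy, and 721 and 9 after 10 cGy.

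The response at 6 h differed between the lines for 90 genes after 100 cGy (52 higher and 38 lower in shRNA cells; 718 at an unadjusted p under 0.05) and for 142 after 10 cGy (82 and 60; 1076). Saa3 differed by 2.08 ± 0.17 after 100 cGy and 1.87 ± 0.17 after 10 cGy, Mmp13 by 1.86 ± 0.16 and 1.74 ± 0.16, the interferon-induced gene Rsad2 by 1.89 ± 0.27 and 2.09 ± 0.27, the lipocalin gene Lcn2 by 1.39 ± 0.24 and 1.35 ± 0.24, and the oncostatin M receptor gene Osmr by 1.35 ± 0.12 and 1.33 ± 0.12. Tnnt2 (-1.47 ± 0.14 and -1.14 ± 0.14) and Tubb3 (-1.42 ± 0.24 and -1.28 ± 0.24) differed the other way, as did Adam12 (-1.20 ± 0.15), the transporter gene Slc6a12 (-1.19 ± 0.26) and Chn1, a Rac-regulating chimaerin (-1.14 ± 0.25), after 100 cGy. After 10 cGy the metalloproteinase inhibitor gene Timp3 (-1.58 ± 0.37), the natriuretic peptide gene Nppb (-1.19 ± 0.21) and Smoc2 (-0.99 ± 0.16) did so. NF-kB genes passed as a list at both doses, with 4 of 25 higher after 100 cGy (5 higher and 1 lower over the list alone) and 6 after 10 cGy (8 and 2), including Vcam1 (0.95 and 1.17). Their adjusted p was 3.58e-04 and 6.68e-05 with an estimated correlation. Both doses share the same untreated arrays, so the 2 results are not independent. No list was tested against 1 untreated time, so how far these list calls rest on the untreated time is not known. The interferon list had 2 of 20 higher at each dose (2 and 5 over the list alone), and adjusted p = 0.12 and 0.0918 with an estimated correlation. 6 other lists at 100 cGy and 8 at 10 cGy passed camera but not with an estimated correlation, where the lowest adjusted p was 0.0887 and 0.0918. In untreated vector cells Saa3, Rsad2 and Lcn2 rose from 2 to 24 h (3.01 ± 0.14, 3.61 ± 0.22 and 2.38 ± 0.20), while in shRNA cells the values were -0.82 ± 0.14, 0.15 ± 0.22 and -0.55 ± 0.20, so the differences of these 3 genes at 6 h rest on the untreated time chosen. Against either untreated time alone, calls held for Osmr (against 2 h cells, 0.87 after 100 cGy and 0.85 after 10 cGy), Tubb3 (-1.32 and -1.18), Adam12 after 100 cGy (-1.09) and Vcam1 after 10 cGy (0.56). Against untreated 2 h cells alone, Lcn2 was -0.08 after 100 cGy and -0.11 after 10 cGy, and after 10 cGy Saa3 was -0.05, Tnnt2 0.02 and Smoc2 0.02, with 57 and 32 genes called. Saa3 (0.16), Rsad2 (0.17), Tnnt2 (-0.30), Slc6a12 (-0.40), Chn1 (-1.0) and Vcam1 (0.34) after 100 cGy and Rsad2 (0.36) and Timp3 (-1.15) after 10 cGy were not called there, nor Nppb (-0.66) against untreated 24 h cells alone. Mmp13 and Smoc2 had means under the low-signal limit of 4.35 in every shRNA group, so no response of shRNA cells can be read for them. Slc6a12 and Chn1 had such means in untreated shRNA cells, taken over both times, and Tnnt2 in untreated vector cells at 24 h. Slc6a12 lost its call without vector 100 cGy replicate 2 (adjusted p = 0.0793), Chn1 without shRNA 100 cGy replicate 3 (0.0718) and Timp3 without vector 10 cGy replicate 2 (0.0678); the 142 genes became 94 without vector 10 cGy replicate 1 and 70 without replicate 2. Without the 3 vector arrays that stood apart the counts were 203 and 368.

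At 24 h after 100 cGy, 2 genes were called in opposite directions in the lines, Saa3 and Ccn5. In shRNA cells Saa3 (chromosome 7, 46711998 to 46719615), an acute-phase serum amyloid gene, rose 3.69-fold (1.88 ± 0.14, adjusted p = 9.28e-12), while in vector cells it fell 1.75-fold (-0.81 ± 0.14, adjusted p = 0.00295). The complement protease gene C1s1 (0.97 ± 0.08, adjusted p = 4.19e-10) and the lipopolysaccharide-binding protein gene Lbp (0.82 ± 0.09, adjusted p = 1.47e-07) rose in shRNA cells, as did the matrix gene Prelp (1.09 ± 0.16), Scara5 (1.0 ± 0.16), the complement gene C1ra (0.73 ± 0.11), the lipid phosphatase gene Plpp3 (0.50 ± 0.08) and the matricellular gene Ccn5 (0.58 ± 0.11; -0.50 ± 0.11 in vector cells). C1ra, Plpp3 and Ccn5 were named there after their values were seen. The difference between the lines passed for Saa3 (2.69 ± 0.20, adjusted p = 6.58e-12), C1s1 (1.30 ± 0.12, adjusted p = 2.00e-09), Lbp (0.97 ± 0.13, adjusted p = 1.42e-05), Ccn5 (1.08 ± 0.15), Scara5 (1.27 ± 0.23) and C1ra (0.91 ± 0.15). The other tested probe set of Scara5 had the opposite sign in shRNA cells and in the difference, not called. C1s1 in vector cells had a value of -0.33 ± 0.09, and Lbp -0.14 ± 0.09, neither called. The NF-kB list was higher in shRNA cells on 1 of 25 members, Saa3, over all genes and over the list alone (adjusted p = 0.00665 with an estimated correlation), and so was its difference between the lines (1 higher, and 1 higher and 1 lower over the list alone; 0.00931).

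**Figure D4:**
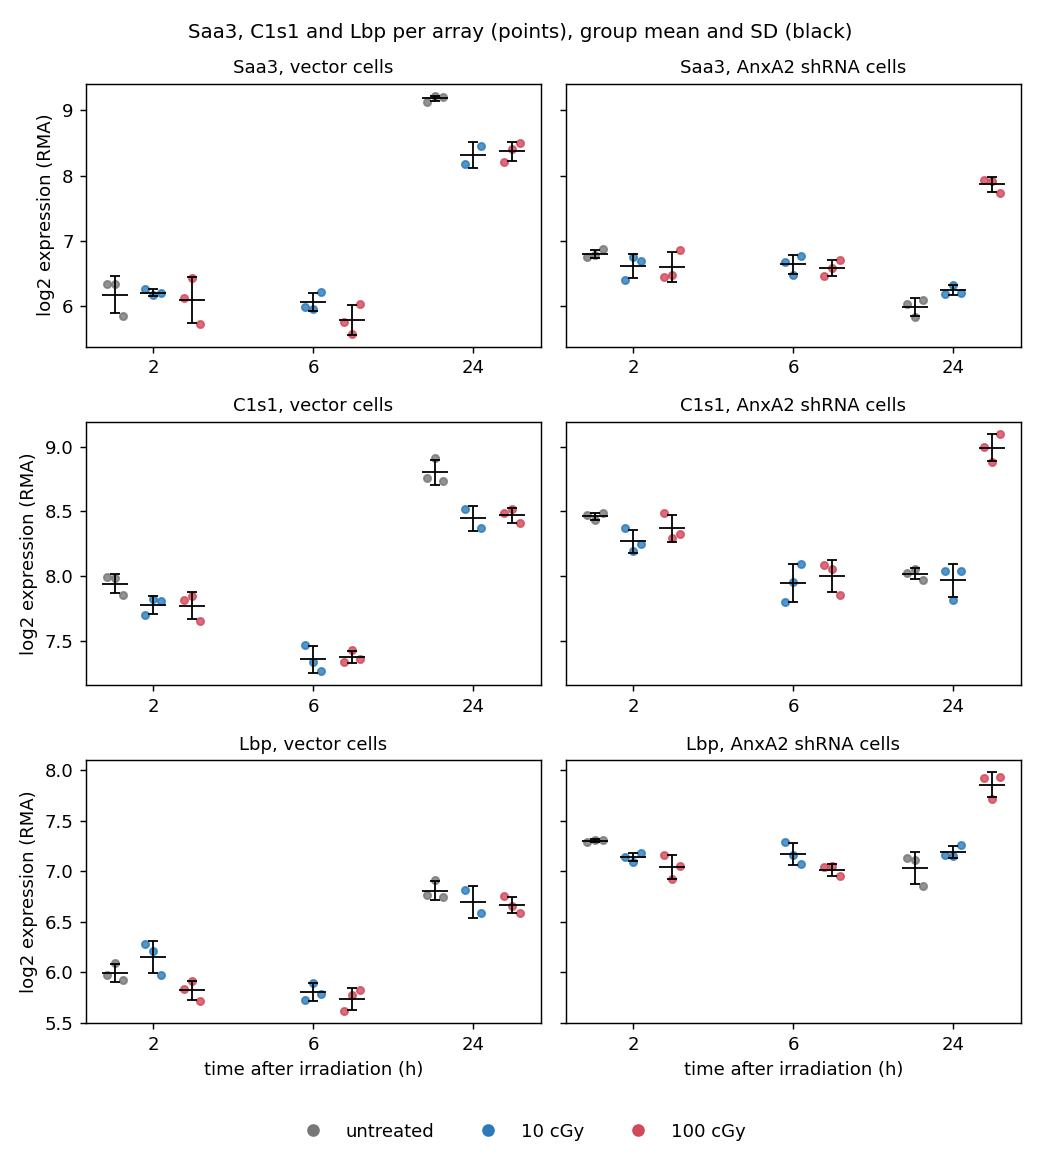
Log2 expression of Saa3, C1s1 and Lbp on each array (points) with group means, by time after irradiation in hours, dose and line. At 24 h after 100 cGy, Saa3 was higher than in untreated cells by 1.88 in shRNA cells and lower by a log2 change of -0.81 in vector cells.

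The p53 target Cdkn1a rose in vector cells at 24 h after 100 cGy (0.82 ± 0.11, adjusted p = 1.03e-04). In shRNA cells it had a value of 0.05 ± 0.11, a difference of -0.77 ± 0.16 (adjusted p = 0.0303). Its log2 signals in untreated cells at 24 h ran from 9.17 to 9.44 in vector and from 9.95 to 10.00 in shRNA cells. After 100 cGy they ran from 10.02 to 10.25 in vector and from 9.95 to 10.08 in shRNA cells. Untreated shRNA cells thus already lay near the level of irradiated vector cells. Dcxr, a dicarbonyl reductase gene in the p53 list (0.55 ± 0.10), Dglucy, a D-glutamate cyclase gene (0.59 ± 0.09), the annexin gene Anxa8 (0.55 ± 0.09) and the chemokine gene Ccl5 (1.05 ± 0.20) also rose in vector cells, and Ccn5 fell (-0.50 ± 0.11). Of 33 p53 targets 2 rose in vector cells (8 over the list alone), and the list moved up (camera adjusted p = 7.13e-14; 9.19e-05 with an estimated correlation). Cholesterol genes (median -0.14) and mitotic genes (median -0.15) moved down as lists in vector cells with no member called (1 lower and 0 over the list alone; adjusted p = 9.88e-05 and 0.0168 with an estimated correlation). The mitotic list did not pass fry (adjusted p = 0.0641). The interferon, annexin and muscle lists passed camera there but had adjusted p = 0.268, 0.437 and 0.104 with an estimated correlation. In shRNA cells the p53 list had 0 of 33 called, also over the list alone (median 0.07, camera adjusted p = 0.0358, but adjusted p = 0.303 with an estimated correlation). The difference in the p53 list between the lines, with 1 of 33 lower, passed camera (adjusted p = 0.00677), though not with an estimated correlation (adjusted p = 0.181). 5 further lists in shRNA cells and 3 in the difference passed camera only, with adjusted p of at least 0.107 with an estimated correlation.

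In all, 6 genes rose and 2 fell in vector cells at 24 h after 100 cGy (288 at an unadjusted p under 0.05), 12 rose and 2 fell in shRNA cells (565), and 7 differed between them (386). The 8 in vector cells were 4 without 100 cGy replicate 1 or 3 and 5 without untreated replicate 1 or 3, 20 without the 3 vector arrays that stood apart, and 17 with a replicate block within line and time. The 14 in shRNA cells were 9 without 100 cGy replicate 2 or untreated replicate 3, 7 without 100 cGy replicate 3, and 27 without those 3 vector arrays, which left 13 in the difference. In vector cells calls were lost on Saa3 without 100 cGy replicate 1 (adjusted p = 0.0645), on Anxa8 without untreated replicate 2 (0.0645), on Dcxr without 100 cGy replicate 3 (0.0599), on Ccl5 without any of 5 arrays (100 cGy replicates 1 and 3 and each untreated one, 0.0529 to 0.187), and on Ccn5 without any of 5 (each 100 cGy replicate and untreated replicates 1 and 3, 0.107 to 0.63). In shRNA cells Ccn5 lost its call without 100 cGy replicate 3 (0.0546) or untreated replicate 2 (0.0529). The difference in Cdkn1a lost its call without any 1 of 9 of its 12 arrays, all but vector 100 cGy replicate 1 and vector untreated replicates 1 and 2 (0.0582 to 0.22).

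At 24 h after 10 cGy, limma called 0 genes in shRNA cells (337 at an unadjusted p under 0.05) and 1 in vector cells, where 2 irradiated arrays were measured. That gene was Saa3 (-0.86 ± 0.16, adjusted p = 0.0262; 88 genes at an unadjusted p under 0.05), and it was also the 1 gene that differed between the lines (1.12 ± 0.21, adjusted p = 0.0463; 125). Interferon (median -0.11), cholesterol (-0.06) and NF-kB genes (-0.04) moved down as lists in vector cells, with adjusted p = 0.0468, 0.00773 and 0.0239 with an estimated correlation. Of their members 1, Saa3, was called, and over the lists alone 1 interferon and 2 NF-kB genes were lower. None of the 3 lists passed fry. The extracellular matrix list, with 0 of 39 called, passed camera only (adjusted p = 0.521 with an estimated correlation). The call on Saa3 was lost in vector cells without 10 cGy replicate 1 (adjusted p = 1) or 3 (0.112) or untreated replicate 1 (0.0968), 2 (0.198) or 3 (0.181), leaving 0 genes each time. The difference between the lines was lost without any 1 of its 11 arrays (0.0631 to 1) and with a replicate block, which left 0.

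The doses were compared directly over both lines (100 minus 10 cGy), without untreated arrays. At 2 h, Mdm2 (0.64 ± 0.08, adjusted p = 2.09e-06), Slc19a2 (0.61 ± 0.07, adjusted p = 2.09e-06) and the long noncoding RNA Neat1 (0.73 ± 0.13, adjusted p = 0.00786) were higher at 100 cGy, and no gene was lower (247 at an unadjusted p under 0.05). Of 33 p53 targets 1 was called (7 over the list alone), with camera adjusted p = 1.18e-17 and adjusted p = 9.54e-06 with an estimated correlation. The 3 genes became 5 without shRNA 100 cGy replicate 2, 14 without vector 10 cGy replicate 3, 12 without the 3 vector arrays that stood apart, 10 with a replicate block within line and time, and 0 with only the compared groups in the fit. Neat1 lost its call without vector 100 cGy replicate 3 (adjusted p = 0.0726) or vector 10 cGy replicate 1 (0.059) or 2 (0.0905).

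At 6 h, genes of mitosis were higher after 100 than after 10 cGy: the kinase genes Aurka (0.44 ± 0.07, adjusted p = 7.26e-04) and Cdk1 (0.28 ± 0.05), the kinetochore gene Cenpf (0.41 ± 0.07), Cdc20 (0.33 ± 0.06), which activates the anaphase-promoting complex, and the spindle gene Ckap2 (0.48 ± 0.07). Mdm2 was higher as well (0.43 ± 0.08, adjusted p = 0.00294), and the uracil glycosylase gene Ung was lower (-0.66 ± 0.11). Of 39 mitotic genes 4 were called, and 22, all higher, when adjusted over the list alone; the list had adjusted p = 8.78e-05 with an estimated correlation. The p53 list was higher with 1 of 33 called, the same over the list alone (adjusted p = 3.60e-04 with an estimated correlation). DNA replication genes passed camera downward, with a median of -0.02 and 3 of 37 lower over the list alone, but had adjusted p = 0.259 with an estimated correlation. In all 6 genes were higher and 1 lower (358 at an unadjusted p under 0.05). Within a line, tested after the data were seen, limma called 8 genes in vector cells and 0 in shRNA cells. At an unadjusted p under 0.05 there were 376 and 299. The dose difference itself differed between the lines for 0 genes (limma, 346 at an unadjusted p under 0.05). Cdc20 lost its call without shRNA 100 cGy replicate 2 (adjusted p = 0.0699), shRNA 10 cGy replicate 1 (0.0689), the array with the Gapdh difference of 1.06, or vector 10 cGy replicate 3 (0.0705). The count of 7 was 19 without the 3 vector arrays that stood apart, none of which is in this comparison, 18 with a replicate block within line and time, and 4 with only the compared groups in the fit.

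At 24 h, over both lines, 10 genes were higher after 100 than after 10 cGy and none lower (217 at an unadjusted p under 0.05). Within a line, tested after the data were seen, limma called 14 genes in shRNA cells and 0 in vector cells (213 and 132 at an unadjusted p under 0.05). Of the 10 genes, Saa3 (0.84 ± 0.11, adjusted p = 6.89e-06) and C1s1 (0.53 ± 0.06, adjusted p = 5.38e-06) had the smallest adjusted p. In shRNA cells alone these differed by 1.63 and 1.03, and the dose difference itself differed between the lines for 3 genes, Saa3 (1.57 ± 0.21, adjusted p = 3.29e-05), C1s1 (1.0 ± 0.13, adjusted p = 1.79e-05) and Lbp (0.70 ± 0.13, adjusted p = 0.0244), in a test added after the data were seen. As lists, p53 targets (median 0.13; 6 of 33 over the list alone), interferon genes (0.17; 7 of 20) and NF-kB genes (0.06; 1 of 25) were higher at 100 cGy, with adjusted p = 1.27e-04, 5.86e-04 and 8.51e-04 with an estimated correlation; over all genes 0, 0 and 1 of their members were called. Extracellular matrix and plasminogen system genes (medians 0.08 and 0.09) were higher and DNA replication genes (-0.05) lower with no member called, over all genes or over the list alone (adjusted p = 0.0265, 0.029 and 0.0265 with an estimated correlation); these 3 did not pass fry. Mitotic and annexin lists passed camera but had adjusted p = 0.134 and 0.134 with an estimated correlation. The 10 genes became 2 without shRNA 100 cGy replicate 1, shRNA 10 cGy replicate 1, vector 100 cGy replicate 3 or vector 10 cGy replicate 3, 3 without shRNA 100 cGy replicate 3 or vector 100 cGy replicate 2, 4 without shRNA 10 cGy replicate 2 or vector 100 cGy replicate 1, and 5 without shRNA 100 cGy replicate 2 or vector 10 cGy replicate 1.

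In untreated cells, averaged over the lines, many genes changed between 2 and 24 h, with 1479 genes higher and 1352 lower at 24 h (40 and 99 at least 2-fold). The hyaluronan synthase gene Has2 was 20.2-fold lower at 24 h (-4.34 ± 0.48, adjusted p = 5.30e-09), and Ccn2 (-3.60 ± 0.42), a connective tissue growth factor, Egr2 (-3.13 ± 0.55), the cytokine gene Il11 (-3.13 ± 0.48) and the cornified envelope gene Lce1f (-3.04 ± 0.14) fell as well. Rsad2 (1.88 ± 0.15), the growth arrest gene Gas1 (1.86 ± 0.16), Hlf (1.79 ± 0.15), Gpnmb (1.75 ± 0.12) and the receptor gene Mrgprf (1.58 ± 0.09) rose. Rsad2 rose in vector cells alone (3.61 ± 0.22, against 0.15 ± 0.22 in shRNA cells, not called; difference -3.46 ± 0.31, adjusted p = 2.37e-10). Of 20 cholesterol synthesis genes 15 rose (16 over the list alone), such as Fdft1 (0.98), Hmgcs1 (0.89) and Idi1 (0.86), the 1 list of 7 called that passed with an estimated correlation (adjusted p = 2.55e-05). Of 26 immediate early genes 18 fell and 3 rose (the same over the list alone), such as Egr1 (-1.61) and Fosl1 (-1.10), and 24 of 39 mitotic genes fell (26 lower and 1 higher over the list alone), such as Kif23 (-0.73). Of 20 interferon genes 12 rose (the same over the list alone), such as Ifit2 (0.88). Of 39 extracellular matrix genes 15 fell and 7 rose (16 and 7 over the list alone), such as the smooth muscle actin gene Acta2 (-1.08) and Thbs1 (-2.26), of 41 actin and adhesion genes 15 fell and 2 rose (16 and 2), such as Cd44 (-0.83), and of 5 muscle genes Tnnt2 fell (-2.53; 2 lower over the list alone). These 6 lists had adjusted p = 0.0648, 0.09, 0.0741, 0.352, 0.0741 and 0.0741 with an estimated correlation, and all 7 passed fry. The Tnnt2 mean in untreated vector cells at 24 h lay under the low-signal limit, so the size of its fall is not exact. Cdkn1a (-0.88 ± 0.08) and Mdm2 (-0.65 ± 0.08) fell from 2 to 24 h. Vector untreated replicate 3 at 2 h, 1 of the arrays that stood apart, is part of this comparison.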

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

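The 2 tests of the 6 h counts in the pattern on 6 h below were chosen only after the result was seen. The tests on Saa3, C1s1 and Lbp name these genes and the 14 genes called in shRNA cells, so they followed those calls. The others in this part were planned before the result.

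The results here are those in which the response to X-rays differed between the lines by the interaction test. After 100 cGy, 1 gene differed at 2 h, 90 at 6 h and 7 at 24 h, and after 10 cGy 1, 142 and 1. At 2 h these were Myl6 after 100 cGy (-0.66) and Ttll3 after 10 cGy (-1.17). At 6 h after 100 cGy, Saa3 (2.08), Rsad2 (1.89), Mmp13 (1.86), Lcn2 (1.39) and Osmr (1.35) had higher and Tnnt2 (-1.47), Tubb3 (-1.42), Adam12 (-1.20), Slc6a12 (-1.19) and Chn1 (-1.14) lower responses in shRNA cells. At 6 h after 10 cGy, Rsad2 (2.09), Saa3 (1.87), Mmp13 (1.74), Lcn2 (1.35) and Osmr (1.33) had higher and Timp3 (-1.58), Tubb3 (-1.28), Nppb (-1.19), Tnnt2 (-1.14) and Smoc2 (-0.99) lower responses. At 24 h after 100 cGy, Saa3 (2.69), C1s1 (1.30), Scara5 (1.27), Ccn5 (1.08) and Lbp (0.97) responded higher and Cdkn1a lower (-0.77) in shRNA cells, and after 10 cGy Saa3 higher (1.12). Against untreated 2 h cells alone the 6 h differences in Lcn2 (-0.08 after 100 and -0.11 after 10 cGy) and, after 10 cGy, in Saa3 (-0.05), Tnnt2 (0.02) and Smoc2 (0.02) changed sign. Those in Saa3, Rsad2, Tnnt2, Slc6a12 and Chn1 after 100 cGy and in Rsad2 (0.36) and Timp3 (-1.15) after 10 cGy were not called, nor was Nppb against 24 h cells alone. Mmp13 and Smoc2 lay under the low-signal limit in every shRNA group. Calls on these genes that end without 1 array stand in the report with the array's name. They are Myl6, Ttll3, Slc6a12 (vector 100 cGy 6 h replicate 2, adjusted p = 0.0793), Chn1 (shRNA 100 cGy 6 h replicate 3, 0.0718), Timp3 (vector 10 cGy 6 h replicate 2, 0.0678), Cdkn1a and Saa3 after 10 cGy at 24 h. With at most 3 arrays in a group, single arrays were not tested against their group; the 3 vector arrays at 2 h that stood apart are described in the report, and no value column was left unused.

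Other splits of the same arrays were used to ask whether a chance split of them would give these counts. With 100 splits the lowest share is 1 of 100, and the shares were not adjusted over the comparisons. The replicates may not be separate cultures, so a chance difference between cultures cannot be judged. For the interaction at 24 h after 100 cGy, 1 of 100 splits, the real one, called as many as its 7 genes, with at most 5 in the others. This argues against a chance split of the arrays as the source of that count. The interaction at 24 h after 10 cGy, with 2 vector arrays in 1 group, was not compared with other splits. For the other 4 interactions chance is not excluded. At 2 h after 100 cGy 12 of 100 splits called at least 1 gene (highest other 796), at 6 h 15 called at least 90 (1397), at 2 h after 10 cGy 17 called at least 1 (31), and at 6 h 13 called at least 142 (1613). Splits that call several times the real count point to a structure of the samples. At 6 h they mix untreated arrays of 2 and 24 h, and 494 genes changed differently with time in the lines, so the 6 h splits cannot judge chance and it stays open there. At 2 h 13 splits at each dose, the real one included, part all pairs of equal replicate number. Of these, no other split called more than 1 gene, so the higher counts came from splits that keep such a pair together. What the structure is was not tested beyond that.

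The line difference in untreated cells covers 48.2% of genes, and 1 of 100 splits called as many as its 4185 genes (highest other 3274). This argues against a chance split of these arrays. A candidate technical source is that the lines differ in chromosome segments gained or lost in culture, which may shift neighbouring genes together. The differences of genes 10 places apart on a chromosome had a correlation of 0.0501 over 8667 genes, barely above the bound of 0.05 set in advance and above the highest of 1000 shuffled gene orders (0.0379), while the change with time gave 0.0148 (highest shuffled 0.0402). At 1, 30 and 100 places apart the line difference had 0.122, 0.0694 and 0.0536 and the change with time 0.0675, 0.0138 and 0.0051. Segments could therefore be part of the line difference; how large a part was not tested. Loss of Anxa2 itself stays open too: with 1 line of each kind it cannot be told apart from other differences between the lines.

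Many genes were called at 6 h against the mean of the untreated times. Averaging a low and a high untreated time is argued against as the whole source, since at least 20.7% of the called genes in each comparison differed in 1 direction from both times. Time in culture stays open: 7 genes differed between the doses at 6 h, few beside the 1305 to 1597 called against untreated cells, which a change with time would give and a radiation response without dependence on dose would give as well. These cannot be told apart, because no untreated 6 h group was measured. 2 of 84 splits, the real one included, called as many genes in each 6 h response. After 100 cGy the real and highest other counts were 1597 and 2555 in vector and 1305 and 2196 in shRNA cells. After 10 cGy they were 1480 and 2737 in vector and 1522 and 2294 in shRNA cells. The higher split sets the 3 untreated 24 h arrays against the rest, a structure of time. Most other splits mix untreated arrays of 2 and 24 h, which adds the change with time to the spread. These splits therefore cannot judge chance, and it stays open.

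Saa3, C1s1 and Lbp rose in shRNA cells at 24 h after 100 cGy, and their response differed from that of vector cells. Against 1 deviating array as the source, the highest adjusted p of the 3 genes with any 1 of the 12 arrays left out was 1.92e-04, and against RNA quality, at least 0.979 of each difference was left with the Gapdh 3' minus 5' difference as a covariate. Against shRNA cultures run further in time, slopes of the change on the 6 to 24 h change after 10 cGy were taken. The slope was 0.662 over the 14 genes called after 100 cGy and 0.0414 over 2054 other time-dependent genes. That time change itself was -0.40 for Saa3, 0.02 for C1s1 and 0.01 for Lbp. Against leukocytes in the cultures, the largest change of a tested leukocyte marker was 0.29 (Lyz2), none was called, and Saa3 rose by 1.88. An effect of Anxa2 level on the late response is possible, but with 1 line of each kind any other difference between the lines could give it as well; a further shRNA, or Anxa2 put back, would test it. A difference between the cultures of these groups that is not tied to time or RNA quality was not tested, and these genes also changed with time in untreated cells.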

How the results depend on the processing

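The fit without the 3 vector arrays that stood apart and the replicate block within line and time were chosen only after the data were seen; the other alternatives were planned. A count is taken as kept here when it is within 1.5 times the count reported.

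The counts with many genes kept their size under most alternatives, and the counts of 10 genes or fewer moved most. Of 23 counts, 23 were kept with a trend and robust variance prior, 22 with a replicate block, 21 without the filter on low values, 20 with the lowest 50% of genes left out, 19 after quantile normalization again, 16 with all probe sets, 12 with only the compared groups in the fit, 11 without the 3 vector arrays and 5 with array weights. Of 257 named gene values, none that was called changed direction under the 8 of these alternatives that give gene values, and 235 to 255 kept direction and side of the threshold (208 of 208 with the lowest 50% left out, where fewer genes were tested). All 101 list calls were kept with a replicate block and 86 without the 3 vector arrays.

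Without the filter the difference at 24 h after 10 cGy had 0 genes and dose at 24 h 5, with more genes to adjust over. With the lowest 50% left out, 10 cGy at 2 h in shRNA cells and its difference between the lines had 0, since Ttll3 is then not tested, and dose at 2 h had 5. Counting all probe sets gave 6964 for the line difference, 4503 for time, 0 for 10 cGy at 24 h in vector cells and for its difference between the lines, 12 for 10 cGy at 2 h in shRNA cells, 24 for dose at 2 h and 5 at 24 h; several probe sets of a gene count separately there. Quantile normalization again gave 8 for 100 cGy at 2 h in vector cells, 2 for 10 cGy at 2 h in shRNA cells, and 0 for the difference after 10 cGy at 2 h and at 24 h; the cause was not tested. The replicate block gave 0 for the difference after 10 cGy at 24 h; the cause was not tested.

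With only the compared groups in the fit, fewer arrays estimate the spread. It gave 0 genes for 100 cGy at 2 h in either line and for their difference, for the difference after 10 cGy at 2 h, for 10 cGy at 24 h in vector cells and for dose at 2 h. It gave 1037 for 100 cGy at 6 h in vector cells, 989 for 10 cGy at 6 h in shRNA cells, 69 for the difference after 10 cGy at 6 h, 4 for dose at 6 h, and 11 for the difference after 100 cGy at 24 h.

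Array weights ran from 0.164 to 7.17, and the estimate stopped before it converged. They gave 1619, 2722 and 283 genes for 100 cGy in vector cells at 2, 6 and 24 h, 204, 2714 and 96 in shRNA cells, and 1733, 516 and 75 for the difference. After 10 cGy they gave 1451 and 2966 at 2 and 6 h in vector cells, 1492 at 2 h in shRNA cells, and 699 and 786 for the difference at 2 and 6 h. They gave 331, 38 and 49 for dose and 4428 for time. For 100 cGy at 2 h in vector cells, other splits of the 6 arrays gave 0 to 1243 genes with array weights, with a median of 368. The other counts were not compared with other splits, and the cause was not tested.

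The 6 h comparisons were also taken against 1 untreated time. Untreated 2 h cells alone gave 717 genes in vector and 723 in shRNA cells after 100 cGy, 510 and 824 after 10 cGy, and 57 and 32 for the differences after 100 and 10 cGy. Called values that changed sign were Cdkn1a in shRNA cells after 10 cGy (-0.0446), the difference in Lcn2 after 100 cGy (-0.0795), and the differences after 10 cGy in Saa3 (-0.0465), Lcn2 (-0.11), Tnnt2 (0.0190) and Smoc2 (0.0195). Untreated 24 h cells alone gave 1965 in shRNA cells after 100 cGy, 2487 in vector cells after 10 cGy, and 283 and 547 for the differences. The construction shows the source, since 2831 genes changed between the untreated times.

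Without the 3 vector arrays at 2 h, which also enter the common estimate of spread, 100 cGy gave 14 and 20 genes in vector cells at 2 and 24 h, 27 in shRNA cells at 24 h, and 5, 203 and 13 for the difference at 2, 6 and 24 h. After 10 cGy there were 10 in vector and 9 in shRNA cells at 2 h, and 7 and 368 for the difference at 2 and 6 h; dose gave 12 at 2 h and 19 at 6 h. The correlation of the lines' responses was -0.00697 after 100 cGy at 2 h, 0.237 after 10 cGy at 2 h and 0.535 at 6 h. The replicate block within line and time gave 21 and 17 for 100 cGy in vector cells at 2 and 24 h, 24 in shRNA cells at 24 h, 7 for 10 cGy at 2 h in shRNA cells, 4 and 11 for the difference after 100 cGy at 2 and 24 h, and 10 and 18 for dose at 2 and 6 h. The cause was not tested for either.

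Leaving out each array in turn gave these lowest and highest counts. For 100 cGy in vector cells they were 2 and 23 at 2 h and 4 and 6 at 24 h, in shRNA cells 0 and 2 at 2 h, 838 and 1270 at 6 h and 7 and 12 at 24 h, and for the difference 0 and 5 at 2 h. For 10 cGy they were 0 and 7 in vector and 1 and 3 in shRNA cells at 2 h, 0 throughout in vector cells at 24 h, and 0 and 4, 70 and 187, and 0 throughout for the difference at 2, 6 and 24 h. For dose they were 2 and 14 at 2 h and 2 and 7 at 24 h. The arrays are named in the report; fewer arrays give less precision, and why single arrays add calls was not tested.

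The correlation of the lines' responses across genes ran from -0.418 to 0.0559 after 100 cGy at 2 h (positive without shRNA 100 cGy replicate 2), from 0.640 to 0.691 at 6 h, and from -0.0934 to 0.173 at 24 h, where it was 0.0283 over all arrays and negative without shRNA 100 cGy replicate 3, vector 100 cGy replicate 1 or 3, or vector untreated replicate 2. After 10 cGy it ran from 0.230 to 0.550 at 2 h (0.494 over all arrays), from 0.535 to 0.620 at 6 h, and from -0.161 to 0.214 at 24 h, where it was 0.0491 over all arrays and negative without shRNA 10 cGy replicate 3, vector 10 cGy replicate 1 or vector untreated replicate 2. Over the genes called in either line it was 0.745 at 6 h after 100 cGy, 0.687 at 6 h after 10 cGy, and -0.623 at 24 h after 100 cGy, over 20 genes; choosing called genes selects large changes. Signal over background limits genes near the bottom of the scale, where changes are compressed: the filter left out those with a log2 mean under 4.35, and tested genes can lie under it in some groups.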

Other observations

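The contrasts within a line in the next paragraph were chosen only after the data were seen, as were the genes named there; the splits and list tests were planned.

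Without any radiation, 494 genes changed differently in the lines between 2 and 24 h in culture. In vector cells the acute-phase and inflammatory genes Saa3 (3.01 ± 0.14), Lcn2 (2.38 ± 0.20), Cxcl1 (1.65 ± 0.20) and Lbp (0.81 ± 0.09), the complement gene C1s1 (0.86 ± 0.09) and the interferon-induced gene Rsad2 (3.61 ± 0.22) rose with time. In shRNA cells Saa3 (-0.82 ± 0.14), Lcn2 (-0.55 ± 0.20), Lbp (-0.27 ± 0.09) and C1s1 (-0.44 ± 0.09) fell, and Rsad2 had a value of 0.15 ± 0.22. The difference between the lines passed for Saa3 (-3.83 ± 0.20, adjusted p = 7.91e-17), Rsad2 (-3.46 ± 0.31, adjusted p = 2.37e-10), Lcn2 (-2.93 ± 0.28), Cxcl1 (-2.97 ± 0.28), C1s1 (-1.30 ± 0.12) and Lbp (-1.08 ± 0.13). Tnnt2 fell more in vector cells (-3.69 ± 0.12) than in shRNA cells (-1.36 ± 0.12), a difference of 2.33 ± 0.17. Its mean in untreated vector cells at 24 h lay under the low-signal limit, so the sizes of that fall and difference are not exact. Vector untreated 2 h replicate 3, which stood apart from its group mates, is among the arrays compared.

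4 lists of general cell functions did not pass camera in the line difference. Members of each were called, as were 48.2% of all tested genes in this comparison. Of 18 heat shock genes 7 were higher and 2 lower in untreated shRNA cells, the same over the list alone (median 0.09, adjusted p = 0.149). Of 22 hypoxia and glycolysis genes 7 were higher and 3 lower, the same over the list alone (median -0.02, mean 0.06, adjusted p = 0.729). Of 28 apoptosis regulators 10 were higher and 9 lower, the same over the list alone (median 0.04, mean -0.08, adjusted p = 0.729). Of 10 reference genes 3 were higher and 3 lower, the same over the list alone (median -0.07, adjusted p = 0.729).

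Most of the remaining counts were compared with other splits of their arrays as well; 10 cGy at 24 h in vector cells, with 2 arrays, was not. For time in untreated cells 1 of 100 splits called as many as 2831 genes (highest other 1887). For dose at 6 h 1 of 100 called as many as 7 (highest other 1). Both shares lie under the bound of 0.05 set in advance, which argues against a chance split of these arrays. A chance difference between cultures cannot be judged, since the replicates may not be separate cultures. For dose at 24 h 2 of 100 called as many as 10, a share under the bound of 0.05 set in advance. But another split called 24, and other splits that part all pairs of equal replicate number reached 8, so chance stays open there. For dose at 2 h chance is not excluded: 14 of 100 splits called at least 3 genes (highest other 1257, which points to a structure of the samples). Splits of that comparison that part all pairs of equal replicate number called 0. For comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. There the counts were 4 for 100 cGy in vector cells at 2 h (5 splits called as many, highest other 390, and 0 among splits that part all pairs) and 8 at 24 h (1 split, highest other 1, and 0 among splits that part all pairs). In shRNA cells they were 2 for 100 cGy at 2 h (2 splits, highest other 188) and 14 at 24 h (1 split, highest other 1). After 10 cGy they were 0 in vector cells at 2 h (limma; 508 at an unadjusted p under 0.05; all 10 splits call at least as many, highest other 403), 1 in shRNA cells at 2 h (1 split, highest other 0) and 0 in shRNA cells at 24 h (limma; 337 at an unadjusted p under 0.05; 10 splits, highest other 0).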
